A study of Mus musculus with 7 samples.

How the data were processed

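RNA from the ventricles of male mice was sequenced after trans-aortic banding (3 TAB libraries) or sham operation (4 Sham libraries). Libraries were polyA-enriched and stranded, per the labels' protocols. The authors deposited 1 table of FPKM values with 23847 gene rows, made with TopHat and Cufflinks on mm10, per the submitters' processing notes, and versions, parameters, the annotation and any scaling between libraries are not given in the sources used here. Each of the 7 columns was matched to its sample by the column name quoted in the sample's description, and groups and replicate numbers come from the sample titles. Of the rows, 747 share a symbol with another row, 27 carry a symbol turned into a date by a spreadsheet, and 0 lie on the mitochondrial chromosome, so mitochondrially encoded genes were not analysed here. Start positions in the table count from 0, since 12105 of 21262 genes compared with RefSeq's GRCm38 annotation began exactly 1 base lower and 714 at the same base; positions are given from 1.

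The FPKM sums of the deposited columns were 510016, 527854, 510097 and 524468 in Sham 1 to 4 and 519844, 535455 and 523646 in TAB 1 to 3. Depth was estimated from genes with a single annotated transcript of 3000 to 6000 bp in GENCODE M21, as the number of fragments for which most low values fell within 5% of 1 to 4 whole fragments. Between 64.9% and 72.4% of the 66 to 77 low values per library did so, where chance gives 21% at a fixed depth, a share that is higher when the depth is chosen to fit. The estimates lay between 10.8 and 12.2 M (mega) fragments, so that low genes rest on few fragments and counts could not be recovered for a count model.

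Values were transformed to log2(FPKM + 1), and rows with an FPKM of at least 1 in at least 3 of the 7 libraries (11601 rows) were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust set), two-sided, with Benjamini-Hochberg adjustment over all tested rows and a threshold of 0.05. All 7 libraries entered the fit without covariates. The 41 gene lists had been fixed before the data were examined. The 37 with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 37 lists. For 5 list genes the table uses an older symbol, found among RefSeq synonyms. The lists of lymphocyte, of Schwann cell and neuron, and of thymus, lung and airway markers had 1, 2 and 0 members above the filter and were not tested, and the highest value of a thymus, lung or airway marker was 0.773 FPKM. The CDK8 module genes and the share of Myh7 were also compared by an exact permutation test over the 35 assignments of 7 libraries, with the absolute difference of group means as statistic.

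The genes named are the 15 with the largest rise and the 15 with the largest fall among called rows whose groups do not overlap and whose mean FPKM in the higher group is at least 5, without predicted genes and pseudogenes; 8 known markers of pressure load; the CDK8 module; and up to 4 members of each list with the smallest adjusted p. Further members are named where a count of 5 or fewer would otherwise be incomplete, and the text says so. Some genes that this rule names are not reported here; they stay in all tests and counts. In simulated data with the means and spreads of the 11601 tested genes and 200 changed genes, 38% of genes changed 1.25-fold were recovered, 76% at 1.5-fold, 94% at 2-fold and 100% at 3-fold, with 7 false calls. These folds are of FPKM + 1, so for low genes they stand for larger changes of FPKM. Far fewer genes were changed than were called in the data, so the rates may differ from those of the reported fit. A simulated list of 30 genes shifted by 0.3 on the log2 scale was recovered, and 3 of 100 unshifted lists had an unadjusted p under 0.05. The simulated genes were drawn independently of each other. That rate therefore does not cover real lists whose members vary together, with estimated correlations of up to 0.71.

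Alternatives set before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean FPKM of 5, median-of-ratios rescaling, quantile normalization, eBayes without trend and robust, array weights, the replicate number as a block, each library left out, and the estimated correlation. Added after seeing the data were a fit without Sham 2 and TAB 3, a fit with an atrial covariate (mean log2 of Sln, Myl7 and Myl4), and a fit without rows that are listed at 0 in some library although the median of their values above 0 is at least 10 FPKM. Some of these rows, such as Snora28 and Snora34, were at 0 in most libraries. There were 8 such rows, of which 4 were tested and 0 called, one of them being Cacna2d1 (listed at 0 in Sham 1 and at 38.6 to 50.3 FPKM in the others). Expression of Xist was under 0.11 FPKM and that of Ddx3y at least 20.5 FPKM in each library, matching the male label.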

Results

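RNA was measured in ventricular tissue of male mice that had undergone either trans-aortic banding (TAB), in which a suture narrows the aorta and raises the load on the left ventricle, or a sham operation in which the suture was not tied. Per the labels' protocols the mice were operated on at 8 weeks of age, and the samples carry an age label of 12 weeks. There were 7 polyA-enriched stranded libraries, 4 Sham and 3 TAB, each with 1 FPKM value (fragments normalized for transcript length and sequencing depth) per gene. The depth implied by the whole-fragment steps of the low values was 10.8, 11.1, 12.2 and 12.1 M (mega) fragments in Sham 1 to 4. It was 11.5, 12.1 and 11.9 M fragments in TAB 1 to 3. At that depth 1 FPKM on a 2 kb transcript corresponded to 21.6 to 24.4 fragments. Labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries. Values below are FPKM as mean ± SD, and log2 fold changes are those of FPKM + 1, TAB minus Sham, which understate the change of low genes.

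The banded ventricles carried the transcripts of a heart under pressure load. Acta1, the skeletal muscle actin of the fetal heart, was 134 ± 23.3 (SD, n = 4) in Sham and 2512 ± 422 (SD, n = 3) in TAB, an 18.7-fold difference (log2 fold change 4.22 ± 0.16 SE, limma adjusted p = 5.97e-05). The natriuretic peptide genes Nppa and Nppb, whose products are released by stretched cardiomyocytes, were 5.39-fold and 4.41-fold higher in TAB (log2 fold changes 2.45 ± 0.54 and 2.12 ± 0.34 SE, adjusted p = 0.0339 and 0.0126). Myh7, the slow fetal myosin heavy chain, was 5.15-fold higher (2.26 ± 0.31, adjusted p = 0.00675), whereas Myh6, the fast adult heavy chain, fell by 0.26 ± 0.04 on the log2 scale (adjusted p = 0.0023). Myh7 made up 1.17% ± 0.115 (SD, n = 4) of the summed Myh6 and Myh7 FPKM in Sham and 6.78% ± 2.86 (SD, n = 3) in TAB (exact permutation p = 0.0286, two-sided, the smallest that 35 assignments can give). The matrix genes Postn and Col1a1 were 4.19-fold and 1.89-fold higher (adjusted p = 0.00536 and 0.000217), and Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 0.48 ± 0.05 (adjusted p = 0.000219). No Sham library overlapped a TAB library in any of these 8 genes. The call of Nppa was lost when any single library other than Sham 2 was left out (adjusted p from 0.065 to 0.087, log2 fold changes from 2.04 to 2.66), and that of Nppb without TAB 1 (adjusted p = 0.052). Without both Sham 2 and TAB 3, the libraries richest in atrial transcripts, Nppb and Postn lost their calls (adjusted p = 0.094 and 0.051).

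**Figure D1:**
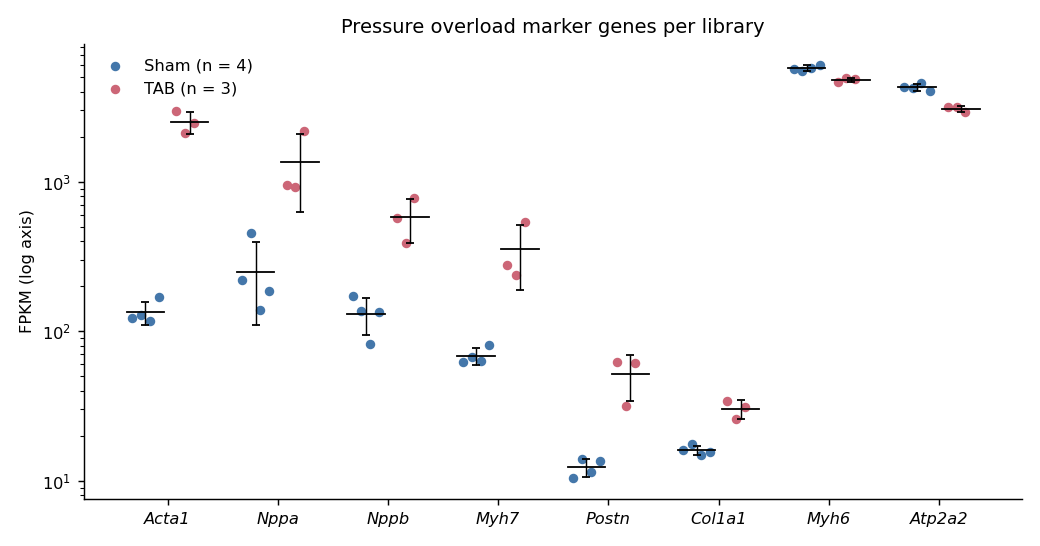
FPKM of 8 genes known to respond to pressure load, on a log axis, in each Sham (blue, n = 4) and TAB (red, n = 3) library, with the mean (horizontal line) and SD (bar). In the 6 genes on the left each TAB library lies above each Sham library, and in Myh6 and Atp2a2 each lies below.

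Banding changed the expression of 2360 of 11601 tested genes, or 20.3%, with 1542 higher and 818 lower in TAB (limma, adjusted p under 0.05). The Sham and TAB libraries did not overlap in 3609 of the 11601 tested genes, or 31.1%, where chance gives 5.71%. The called genes, which were selected for a difference, made up 2287 of the 3609. Most changes were small, since 44 genes rose and 5 fell by a log2 fold change of at least 1. The 15 largest rises included those of Acta1, Nppa, Myh7, Nppb and Postn. The others were those of the cartilage intermediate layer protein gene Cilp (1.63 ± 0.307 to 14.2 ± 6.84), the stretch-responsive ankyrin repeat gene Ankrd1 (597 ± 18.8 to 2641 ± 620), the aquaporin Aqp8 (1.35 ± 0.258 to 8.86 ± 1.96), Mfap4, Thbs4, the protease inhibitor Timp1, Wisp2, Col8a1, the fast skeletal myosin-binding protein Mybpc2 and Cpxm2, with log2 fold changes from 1.48 to 2.42. Among the genes with large falls, the uncoupling protein gene Ucp3 went from 48.8 ± 14.3 to 22.1 ± 4.21 and the carboxylesterase Ces1d from 87.2 ± 4.16 to 41.3 ± 4.75. Acot1, Pdp2 (a phosphatase that activates pyruvate dehydrogenase), Pfkfb1, Phkg1, the monoamine oxidase Maob, the phospholipase Pla2g5, Lgals4, the potassium channel Kcnj3, the vessel growth factor Angpt1, Cenpf, Gal3st3 and Sorcs2 fell by 0.76 to 1.18. Acot1 and Ces1d have close paralogs that can share reads, so their values are less certain.

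The numbers of calls moved with the libraries and the scaling. Without TAB 1, 1450 genes were called (875 higher), without TAB 3 the lower calls came to 545, and without Sham 2 and TAB 3 1354 were called (959 higher, 395 lower). The excess of higher calls was absent under median-of-ratios rescaling (1126 higher, 1190 lower) and under quantile normalization (1045 higher, 1225 lower). Of the named genes, Thbs4 lost its call without any of 5 libraries (adjusted p from 0.079 to 0.113, each Sham library and TAB 1), Lgals4 without Sham 1, Sham 2, Sham 3, TAB 1 or TAB 3 (0.053 to 0.091) and Ucp3 without any library other than Sham 4 (0.070 to 0.133) and with the atrial covariate (0.077). Of the 37 gene lists 19 passed camera, which compares a list with other genes, and 18 passed fry, which asks whether the members of a list themselves differ. Lists of oxidative phosphorylation (fry adjusted p = 0.069), cardiac transcription factors (0.18) and the interferon response (0.13) passed camera only, and those of the adult sarcomere (0.0147) and skeletal muscle (0.0013) passed fry only.

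Genes of cardiac hypertrophy and the fetal heart rose together. Of 18 measured members 15 were higher in TAB, 0 lower and 3 not called (16 higher when adjusted over the list alone), with a median log2 fold change of 1.24. The list stood out from other genes (camera adjusted p = 7.6e-11, and adjusted p = 0.33 with an estimated correlation). Beside Acta1, Ankrd1 and Mybpc2, the intermediate filament gene Des rose from 891 ± 34.9 to 1191 ± 84.5. The genes of the adult sarcomere, the contractile unit of muscle, went both ways: of 20 members 7 were higher, 4 lower and 9 not called (9 higher and 5 lower when adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.28, and 0.047 towards higher under quantile normalization). The stretch-sensing Z-disc gene Csrp3 rose from 1579 ± 50.3 to 2456 ± 106, Tnnc1 (cardiac troponin C) from 3928 ± 174 to 5219 ± 192, Myoz2 by 0.33 ± 0.04 and Mybpc3 by 0.35 ± 0.05 on the log2 scale. The 4 that fell were Myh6, Tnni3 (-0.24 ± 0.05 SE), Nebl (-0.30 ± 0.07) and Tnnt2 (-0.16 ± 0.04), of which the last 3 were chosen after their values were seen. Tnnt2 lost its call without Sham 2, Sham 4, TAB 1 or TAB 3 (adjusted p from 0.053 to 0.112) under quantile normalization (adjusted p = 0.43) and under eBayes without trend and robust (0.088).

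Extracellular matrix genes rose as a group. Of 32 fibrillar and matricellular matrix genes 28 were higher in TAB, 0 lower and 4 not called (31 higher when adjusted over the list alone), with a median log2 fold change of 0.82. Its camera test passed (adjusted p = 5.77e-17, and adjusted p = 0.33 with an estimated correlation). Sparc rose from 144 ± 6.25 to 265 ± 21.5, the proteoglycan Bgn from 81.4 ± 3.77 to 180 ± 23.8, Col1a1 from 16.0 ± 1.10 to 30.2 ± 4.19 and Col8a1 from 5.09 ± 0.296 to 18.1 ± 4.78. Basement membrane genes were higher in 8 of 16, lower in 1 and not called in 7 (11 and 1 adjusted over the list alone, median 0.28, camera adjusted p = 0.0005, and adjusted p = 0.43 with an estimated correlation). The collagen IV genes Col4a1 and Col4a2 rose by 0.71 ± 0.10 and 0.63 ± 0.08, and the laminin gene Lama5 fell by 0.53 ± 0.08. Of 16 genes of myofibroblast activation, the state in which fibroblasts contract and secrete matrix, 11 rose, 1 fell and 4 were not called (15 and 1 adjusted over the list alone, median 0.54, camera adjusted p = 3.05e-06, and adjusted p = 0.18 with an estimated correlation). The myofibroblast list shares Postn, Cthrc1 and Lox with the matrix list, so its rise is not wholly separate from that of the matrix genes. Wisp2 was 4.45-fold and the transcription factor gene Meox1 1.05 ± 0.14 log2 units higher, and the smooth muscle genes Tagln and Cnn1 rose by 0.57 ± 0.08 and 0.66 ± 0.10. The member that fell was the growth factor Fgf2 (-0.51 ± 0.14, chosen after its values were seen), whose call was lost without Sham 2, Sham 3 or TAB 3 (adjusted p from 0.063 to 0.092) or without a filter (0.060).

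Marker lists of fibroblasts, of macrophages and monocytes, and of smooth muscle and pericytes were higher too, and that of endothelial cells was not. Of 14 fibroblast markers 8 were higher, 0 lower and 6 not called (8 adjusted over the list alone, median 0.31, camera adjusted p = 0.00034, and adjusted p = 0.38 with an estimated correlation), among them Cd34 (46.0 ± 1.17 to 74.1 ± 5.16), Smoc2 and Pi16. Of 17 macrophage and monocyte markers 8 were higher, 0 lower and 9 not called (12 adjusted over the list alone, median 0.32, camera adjusted p = 0.00154, and adjusted p = 0.44 with an estimated correlation). Tyrobp, a signalling adaptor of myeloid cells, rose from 15.7 ± 1.68 to 20.9 ± 1.80, and Ms4a7 from 0.922 ± 0.258 to 2.16 ± 0.322. Only 2 macrophage markers were called without TAB 1, 3 without TAB 3 and 4 without Sham 1 or Sham 3. Without a filter 4 of 20 were called, and 4 were called without both Sham 2 and TAB 3. Smooth muscle and pericyte markers were higher in 7 of 14, lower in 1 (Abcc9, which also encodes a potassium channel subunit of cardiomyocytes) and not called in 6 (10 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.00231, and adjusted p = 0.23 with an estimated correlation), with Mcam up by 0.56 ± 0.05 and Cspg4 by 0.59 ± 0.07. The smooth muscle and pericyte list shares Des with the hypertrophy list and Acta2, Tagln and Cnn1 with the myofibroblast list, so its rise is not particular to those cells. Endothelial markers were higher in 7 of 18, lower in 1 and not called in 10 (7 and 1 adjusted over the list alone), with a median of 0.07 that did not differ from other genes (camera adjusted p = 0.52). Egfl7 rose by 0.49 ± 0.07, Prox1 fell by 0.39 ± 0.07, and without TAB 1 only 3 endothelial markers were higher and 2 lower.

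Genes of mitochondrial fuel oxidation fell as a group, those of fatty acid oxidation among them. Of 30 fatty acid oxidation genes 28 were lower in TAB, 0 higher and 2 not called (28 lower when adjusted over the list alone), with a median log2 fold change of -0.36. Its camera test passed (adjusted p = 2.49e-21, and adjusted p = 0.18 with an estimated correlation). Hadha, a subunit of the trifunctional protein of beta-oxidation, went from 541 ± 25.7 to 394 ± 5.49, Acadm, the medium-chain acyl-CoA dehydrogenase, from 892 ± 24.5 to 687 ± 7.17, Decr1 from 215 ± 7.24 to 154 ± 7.76 and Acaa2 from 809 ± 29.5 to 565 ± 44.6. Branched-chain amino acid and ketone catabolism genes were lower in 15 of 19, higher in 1 and not called in 3 (16 and 1 adjusted over the list alone, median -0.30, camera adjusted p = 7.6e-11). This was the only list whose call held with an estimated correlation (adjusted p = 0.0252). Aldh6a1 fell by 0.39 ± 0.04, Ivd by 0.38 ± 0.04 and Mccc2 by 0.36 ± 0.04. The exception was the ketone body enzyme Bdh1, which rose from 38.2 ± 5.03 to 74.5 ± 4.57. Of 20 genes of the tricarboxylic acid cycle 15 were lower, 0 higher and 5 not called (17 lower adjusted over the list alone, median -0.16, camera adjusted p = 3.08e-09, and adjusted p = 0.18 with an estimated correlation), including the citrate synthase gene Cs (675 ± 15.4 to 549 ± 12.0), Idh3g, Idh3a and Suclg2. That count was 8 without TAB 1, 9 without TAB 3 and 8 under eBayes without trend and robust.

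**Figure D2:**
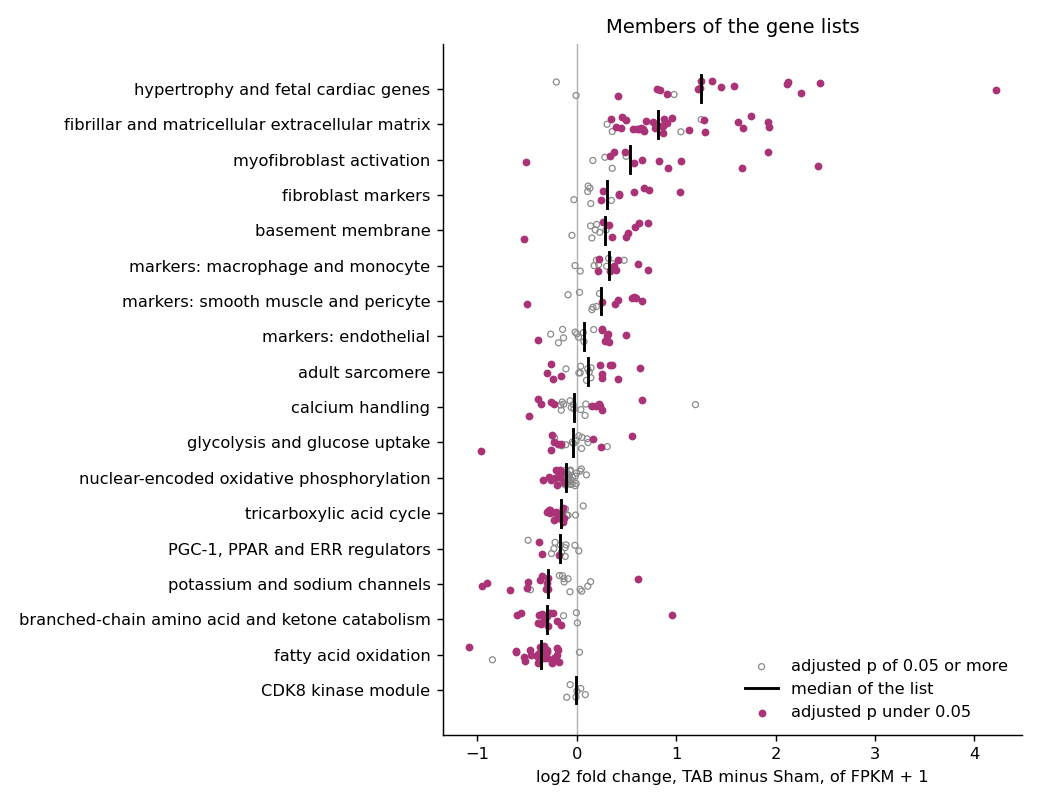
Log2 fold change of FPKM + 1 (TAB minus Sham) of each tested member of 18 gene lists, with filled points for adjusted p under 0.05, open points for the others and a black line at the median of each list. The hypertrophy and matrix lists lie to the right of 0, with medians of 1.24 and 0.82, and the fatty acid oxidation list to the left with a median of -0.36.

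Fewer of the oxidative phosphorylation genes encoded in the nucleus were called. Of 52 members 14 were lower, 0 higher and 38 not called (19 lower adjusted over the list alone), with a median of -0.11 (camera adjusted p = 3.27e-10, and adjusted p = 0.47 with an estimated correlation). The largest values among the named members were those of Sdha (-0.34 ± 0.04), Ndufs1 (-0.26 ± 0.04) and Atp5a1 (-0.22 ± 0.04), while Atp5b (-0.19 ± 0.04) went to 0.03 under quantile normalization (adjusted p = 0.51). The count of lower members was 30 under median-of-ratios rescaling and 25 under quantile normalization, 31 without TAB 2, 9 without Sham 2 or Sham 4, 6 without TAB 1, 7 without TAB 3 and 7 under eBayes without trend and robust. It was 4 without both Sham 2 and TAB 3. Of 14 regulators of mitochondrial genes of the PGC-1, PPAR and ERR families 3 were lower, 0 higher and 11 not called (8 lower adjusted over the list alone, median -0.17, camera adjusted p = 1.93e-05, and adjusted p = 0.085 with an estimated correlation), and 6 or 8 were lower under the same 2 scalings. Rxrg fell by 0.35 ± 0.04 and the coactivator gene Ppargc1a by 0.38 ± 0.06. Perm1 (listed under an older symbol) fell by 0.18 ± 0.04, a call lost without TAB 1 (adjusted p = 0.084) and under eBayes without trend and robust (0.051). Genes of glycolysis and glucose uptake went both ways, with 3 of 21 higher, 6 lower and 12 not called (5 and 7 adjusted over the list alone, median -0.03, camera adjusted p = 0.081). Ldhb, Pfkm, Pfkfb1 and Pfkl were lower by 0.25 ± 0.04, 0.23 ± 0.04, 0.96 ± 0.18 and 0.26 ± 0.06. The 3 that rose were Pfkp (0.56 ± 0.13), Pgam2 (0.24 ± 0.06) and Gapdh (0.16 ± 0.04), chosen after their values were seen. Pfkp lost its call without TAB 1 (adjusted p = 0.062), Pgam2 without TAB 2 (0.062), and Gapdh without Sham 1, Sham 3, TAB 1 or TAB 3 (0.051 to 0.099), so that 1 was higher without TAB 1. Median-of-ratios rescaling also ended the calls of Pgam2 (adjusted p = 0.052) and Gapdh (0.094), as did eBayes without trend and robust (0.052 and 0.076), each leaving 1 higher. Under quantile normalization the log2 fold change of Gapdh was 0.08 (adjusted p = 0.19). Without Sham 1 or TAB 3 the glycolysis list was called lower (camera adjusted p = 0.0447 and 0.0343), as it was without both Sham 2 and TAB 3 (0.0308).

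Ion channel genes fell and calcium handling genes were mixed. Potassium and sodium channel genes were lower in 11 of 23, higher in 1 and not called in 11 (13 and 1 adjusted over the list alone, median -0.29, camera adjusted p = 3.11e-07, and adjusted p = 0.18 with an estimated correlation). Kcnj3 went from 27.1 ± 2.75 to 14.0 ± 2.07, the silent subunit gene Kcnv2 from 3.54 ± 0.600 to 1.36 ± 0.364, Abcc9 from 76.3 ± 1.62 to 53.7 ± 3.45 and the inward rectifier Kcnj2 from 13.9 ± 0.577 to 9.63 ± 1.06. Of 24 calcium handling genes 6 were higher, 5 lower and 13 not called (6 each adjusted over the list alone, median -0.03, mean 0.03, camera adjusted p = 0.14). Atp2a2, its inhibitor Pln (-0.25 ± 0.04), the histidine-rich calcium-binding gene Hrc (-0.39 ± 0.04), the calcium release channel Ryr2 (-0.36 ± 0.06) and Cacna1c (-0.23 ± 0.06) fell, while S100a1 rose by 0.25 ± 0.03. Ryr2 and Cacna1c were chosen after their values were seen. Cacna2d1, listed at 0 in Sham 1 and at 38.6 to 50.3 FPKM in the other libraries, gives this list its highest log2 value (1.19), which comes from that 0 and is not read as a change. Pln lost its call under quantile normalization (adjusted p = 0.087), Cacna1c without TAB 2 or TAB 3 (adjusted p = 0.060 and 0.077), and the count of higher members was 2 without TAB 1 or TAB 3. Without both Sham 2 and TAB 3 that count was 1.

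Most regulators of splicing and transcription were not called, as held for all tested genes. Of the 11601 tested genes 20.3% were called, 1542 higher and 818 lower. Of 43 splicing regulators 5 were lower, 1 higher and 37 not called, also when adjusted over the list alone (median 0.00, camera adjusted p = 0.11, and 0.034 towards lower under median-of-ratios rescaling). Of those that fell, Rbfox1 went from 12.2 ± 1.10 to 7.36 ± 0.861, Mbnl2 from 58.7 ± 0.763 to 48.5 ± 1.39, Rbm24 from 68.7 ± 2.43 to 59.7 ± 1.03, Rbm38 from 75.3 ± 4.67 to 64.0 ± 2.56 and Rbm20 from 45.6 ± 1.52 to 40.1 ± 0.944. The muscle kinase gene Srpk3 rose by 0.32 ± 0.07. Rbm38 and Rbm20 were chosen after their values were seen and lost their calls without TAB 1 (adjusted p = 0.066 and 0.073), which left 3 lower members. Of 25 cardiac transcription factor genes 5 were lower, 0 higher and 20 not called, also when adjusted over the list alone (median -0.04, camera adjusted p = 0.0296, and adjusted p = 0.43 with an estimated correlation), and the call of the list was lost without Sham 4 (camera adjusted p = 0.055, 2 members higher) or TAB 2 (0.13, 1 higher and 2 lower). It was also lost under quantile normalization (0.058), with array weights (0.056), with the replicate block (0.051) and at a mean FPKM of at least 5 (0.074). Without both Sham 2 and TAB 3 only 1 transcription factor gene was lower. Tbx5 fell by 0.33 ± 0.06 and Hopx by 0.31 ± 0.07. Mef2a and Foxo3 were lower by 0.37 ± 0.09 and 0.30 ± 0.07, calls that were lost without TAB 2 (adjusted p = 0.051 and 0.053) or TAB 3 (0.058 and 0.069). Hdac9 (-0.35 ± 0.10), the other lower member, was chosen after its values were seen and lost its call without Sham 1, Sham 2, TAB 1 or TAB 2 (adjusted p from 0.074 to 0.0985) or without a filter (0.068).

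The series is about Cdk8, the kinase of a Mediator submodule that regulates transcription, and its alternative splicing in heart failure. Its gene lies on chromosome 5 from 146231675 to 146302874 (mm10). Cdk8 was 6.40 ± 0.312 (SD, n = 4) in Sham and 6.85 ± 0.254 (SD, n = 3) in TAB, a log2 fold change of 0.09 ± 0.06 SE with a 95% interval from -0.05 to 0.23 (limma adjusted p = 0.38). The exact permutation test gave p = 0.114 for Cdk8 and 0.27 after adjustment over the 7 genes of the module. The table holds 1 row for the gene, so the levels of its splice forms were not analysed here. None of the other 5 module genes above the expression filter differed between the groups past the threshold. The log2 fold changes were -0.01 ± 0.08 for the paralog Cdk19, 0.04 ± 0.09 for the cyclin gene Ccnc, 0.00 ± 0.07 for Med12, -0.07 ± 0.06 for Med13 and -0.10 ± 0.07 for Med13l. Of the 6 genes tested with limma 0 had an unadjusted p under 0.05, and the list did not differ from other genes (camera adjusted p = 0.52). Med12l lay below the expression filter, at 0.861 ± 0.0821 in Sham and 0.561 ± 0.0899 in TAB (exact permutation p = 0.0286, 0.20 adjusted over the 7 genes). Each TAB library lay below each Sham library. That p is the smallest 35 assignments can give, so Med12l could not pass that test by itself after adjustment over 7 genes. In the limma fit without a filter 0 of the 7 module genes were called, and Med12l had a log2 fold change of -0.25 (limma adjusted p = 0.059). Of 26 core Mediator subunits 4 were higher, 0 lower and 22 not called, also when adjusted over the list alone (median 0.08, camera adjusted p = 0.89). Med10 rose by 0.40 ± 0.06, while Med27 (0.24 ± 0.06), Med11 (0.47 ± 0.13) and Med7 (0.27 ± 0.08) lost their calls in some fits. Med27 lost it without TAB 3 (adjusted p = 0.064), Med11 without Sham 3, TAB 1 or TAB 3 (0.062 to 0.102) and Med7 without Sham 2, Sham 3, Sham 4 or TAB 1 (0.057 to 0.13). Quantile normalization ended all 3 of these calls (0.053 to 0.076), no filter those of Med11 (0.060) and Med7 (0.055), and median-of-ratios rescaling that of Med7 (0.053). Without Sham 3, TAB 1 or TAB 3 2 core subunits were higher, and under quantile normalization 1 was higher and 1 lower.

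**Figure D3:**
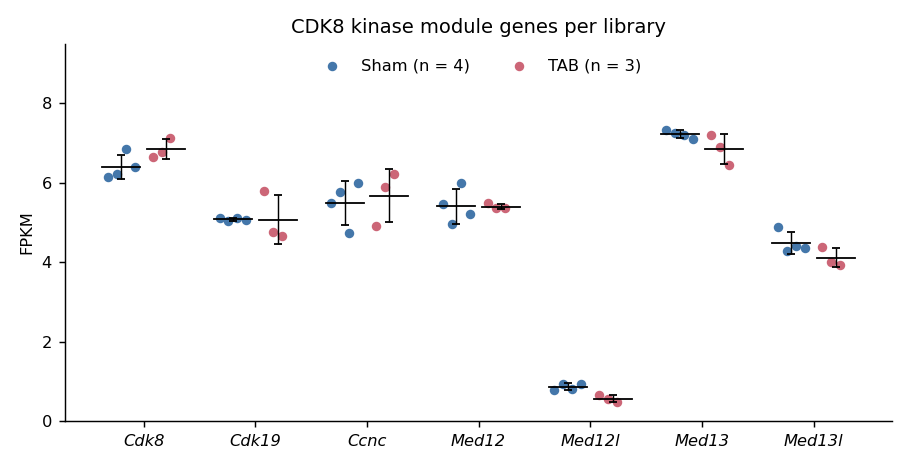
FPKM of the 7 genes of the CDK8 kinase module in each Sham (blue, n = 4) and TAB (red, n = 3) library, with the mean (horizontal line) and SD (bar). The Cdk8 values of the groups overlap, with means of 6.40 and 6.85, and Med12l is the lowest of the 7.

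Transcripts of the atria were present at different levels in the ventricular libraries. Myl7, the atrial myosin light chain, was 26.5, 146, 69.2 and 17.6 FPKM in Sham 1 to 4 and 41.8, 14.9 and 164 in TAB 1 to 3, and Sln and Myl4 were also highest in Sham 2 and TAB 3. Of 12 tested atrial markers 2 were higher in TAB (Nppa and Pam), 4 lower and 6 not called, also when adjusted over the list alone. The median was -0.06, the mean 0.09 and the camera adjusted p 0.10, and the list was called lower without TAB 3 (camera adjusted p = 0.0075) and without both Sham 2 and TAB 3 (0.039). Pam rose by 0.54 ± 0.08, and Nppa lost its call without any library other than Sham 2 (adjusted p from 0.065 to 0.087). Kcnj3, Chrm2, Tbx5 and Stard10, which ventricles also express, were the 4 lower members (-0.91 ± 0.10, -0.46 ± 0.07, -0.33 ± 0.06 and -0.57 ± 0.11). Of 7 red blood cell genes 2 were higher and 5 not called (4 adjusted over the list alone, median 0.59, camera adjusted p = 0.0411, and adjusted p = 0.38 with an estimated correlation). Hba-a1, a globin gene with a near-identical copy, was 181 ± 29.3 in Sham and 301 ± 42.5 in TAB, and Alas2 lost its call when any single library other than Sham 4 was left out (adjusted p from 0.059 to 0.15), and also without a filter, at the smaller pseudocounts and under both rescalings (0.050 to 0.064). The call of the red blood cell list was lost without Sham 1, Sham 2 or TAB 2 (camera adjusted p from 0.061 to 0.14), without a filter (0.16), with array weights (0.059) and at a mean FPKM of at least 5 (0.093). Without both Sham 2 and TAB 3 0 of its members were called. Of 6 skeletal muscle genes Acta1 and Mybpc2 were higher and 4 not called (3 higher adjusted over the list alone, camera adjusted p = 0.19, and 0.0077 at a mean FPKM of at least 5). Without TAB 2 3 skeletal muscle genes were higher and 1 lower. Of 3 neutrophil genes 0 were called, also when adjusted over the list alone, and 0 had an unadjusted limma p under 0.05 (camera adjusted p = 0.96). Of 5 epicardium and valve genes Prg4 rose (0.60 ± 0.15) and 4 were not called, also when adjusted over the list alone (camera adjusted p = 0.63). Prg4 lost its call without TAB 1 or TAB 3 (adjusted p = 0.077 and 0.072). Of 6 adipocyte genes Plin4 fell by 0.36 ± 0.07 and 5 were not called (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.65), and without Sham 2 or Sham 3 1 was higher.

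**Figure D4:**
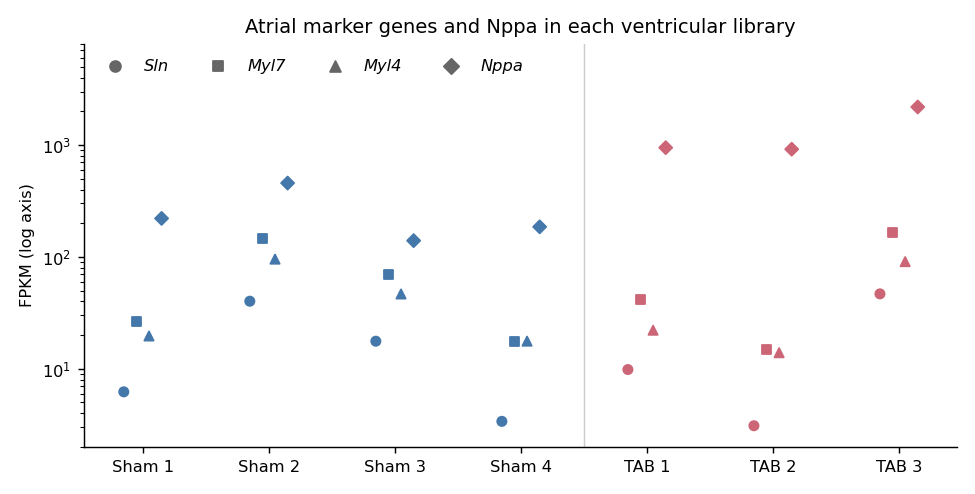
FPKM of the atrial marker genes Sln, Myl7 and Myl4 and of Nppa, on a log axis, in each of the 4 Sham (blue) and 3 TAB (red) libraries. Sln, Myl7 and Myl4 are highest in Sham 2 and TAB 3, and Nppa in each TAB library lies above each Sham library.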

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

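The tests of chance, of cardiomyocyte content, of scaling and of the spread of Nppa were chosen after the results were seen, as was the atrial covariate for the Nppa difference, though before its own result was known. Within the Sham group of 4, 7 results among 182 genes and 37 lists had 1 library far from the others. This was measured as its gap to the nearest library over the range of the group. Chance alone flags about 1 in 20 of independent results, so the count of 7 shows no excess. The genes and lists share members and the measure ignores the size of a difference. The count therefore does not show that any single flag is chance.

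The interferon response list stood out in Sham 4, with a mean log2(FPKM + 1) of 3.03 against 2.43 to 2.51 in the other Sham libraries (gap 0.867 of the range). Iigp1 was 73.4 FPKM in Sham 4 and 17.9 to 21.9 in the other Sham libraries, and Igtp 63.3 against 7.95 to 9.83. Endothelial markers were lowest in Sham 4 (4.60 against 4.76 to 4.78, gap 0.903). Des was highest in Sham 4 (943 FPKM against 867 to 879, gap 0.837), as was Chrm2 (37.4 against 34.8 to 35.2, gap 0.863). Splicing regulators were lowest in Sham 3 (5.00 against 5.04, gap 0.912) and cardiac transcription factors in Sham 1 (3.86 against 3.92 to 3.93, gap 0.887). Idh3g was highest in Sham 3 (423 FPKM against 404 to 406, gap 0.932).

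Fatty acid oxidation genes were lower and matrix genes higher in TAB. As the whole cause, fewer cardiomyocytes per unit of tissue RNA would lower all abundant cardiomyocyte transcripts alike, but the median of the adult sarcomere genes lay 0.48 above that of the fatty acid oxidation genes (95% bootstrap interval over genes 0.36 to 0.60). Scaling of the libraries as the whole cause would shift both lists alike, but the median of the matrix genes lay 1.18 above that of the fatty acid oxidation genes (95% bootstrap interval over genes 1.00 to 1.31). Under median-of-ratios rescaling, which lowers TAB relative to Sham, 28 matrix genes were still called higher (median 0.77). Both intervals resample genes as if independent and carry no spread between libraries. The opposite directions of the matrix and fatty acid oxidation lists were known before they were compared. A larger share of fibroblasts, as the whole cause of the matrix rise, would raise fibroblast markers about as much. Their median was 0.31 (8 of 14 higher) against 0.82. Median shifts in TAB 1 to 3 were 0.38, 0.17 and 0.32 for these markers and 1.04, 0.51 and 0.86 for matrix genes. The markers rose less than the matrix genes, but both lists had their smallest shift in TAB 2. This comparison was not set beforehand and has no interval. It also assumes markers as particular to fibroblasts as the matrix genes are, which was not tested. A larger share of fibroblasts, as a part or the whole of the cause, therefore stays open. A part from fewer cardiomyocytes or from scaling stays open too. A change of expression within cardiomyocytes under pressure load, the biological difference the design names, was not tested and stays open.

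Nppa was higher in TAB and also varied within groups. Atrial tissue in the samples is a possible source, since atria express Nppa at high levels, but with the mean of Sln, Myl7 and Myl4 as a covariate the log2 fold change of Nppa was 2.47 (95% interval 1.38 to 3.55). The spread within groups is a different matter. Deviations of Nppa from the group means went with those of the atrial markers over the 7 libraries (Pearson r = 0.74, exact within-group permutation p = 0.0625, one-sided; Spearman rho = 0.50, exact permutation p = 0.15), and without TAB 3 and Sham 2, the libraries farthest from the median, r was -0.57. Whether atrial tissue sets that spread cannot be told apart from other causes, because the relation rests on these 2 libraries.

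More genes were called higher than lower in TAB. With median-of-ratios rescaling 48.6% of the calls were higher, against 65.3% as deposited, but that rescaling brings the median log2 fold change of all genes from 0.05 to 0.00 and so evens out the calls by its construction. Scaling and a real excess of induced genes in banded hearts therefore cannot be told apart here. A length bias that reverses between short and long transcripts is unlikely to produce the excess. The share of higher calls was 68.5% in the shortest, 69.95% in the middle and 58.2% in the longest of 3 equal groups of genes (length known for 93.9%). It was lowest among the longest, so a part from length stays open.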

How the results depend on the processing

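The test of other splits and the fits without Sham 2 and TAB 3, with an atrial covariate and without the rows listed at 0 in some library were chosen after seeing the data. Of 35 splits of the 7 libraries into 4 and 3, 1, the real one, gave as many called genes (2360, against 2 in the highest other split). A share of 1 in 35 is the smallest this test can give, so chance is unlikely but cannot be excluded. Each other split mixes Sham and TAB libraries, so the difference between the groups adds to its spread and lowers its count. Leaving out each library in turn gave 1450 to 2078 called genes (875 to 1361 higher, 545 to 717 lower), 17 to 22 called lists and 6 to 8 of the 8 pressure load markers. The fewest genes in all, higher genes and markers were called without TAB 1, the fewest lower genes without TAB 3 and the fewest lists without TAB 2. Fewer libraries lower the power. Without Sham 2 and TAB 3 1354 genes were called (959 higher, 395 lower) and 36 named genes lost their calls, again with fewer libraries. Lists called went from 19 to 1 with an estimated correlation, which allows for members that vary together. Such variation is not the whole reason. The list of PGC-1, PPAR and ERR regulators had an estimated correlation of -0.06, and its unadjusted camera p still went from 4.7e-06 to 0.0046. Apart from the replicate block, the other alternatives kept the numbers of genes, lists and markers called within 1.5 times, from 1884 to 2543 genes in all. Which genes were called changed more. Only 1849 of the 2270 genes called under quantile normalization were also called in the reported fit. Under median-of-ratios rescaling 1944 of 2316 were. Cdk8 was not called under any alternative (log2 fold changes from 0.03 to 0.11, adjusted p from 0.28 to 0.80). With the replicate number as a replicate block 1892 genes and 4 of the 8 markers were called, Nppa, Nppb, Myh7 and Postn losing their calls (adjusted p from 0.063 to 0.24) at similar log2 fold changes. The list of cardiac transcription factors lost its call too (camera adjusted p = 0.051). Labels do not say what the number stands for. Only Sham has a number 4, so Sham 4 adds nothing to the difference in the block fit (Nppa log2 fold change 2.35, as without Sham 4). Without Sham 4 in the unpaired fit, Nppa also lost its call (limma adjusted p = 0.083), but Nppb, Myh7 and Postn kept theirs and 2078 genes were called. The missing library may therefore account for the lost call of Nppa but not, by itself, for those of Nppb, Myh7 and Postn. Deviations of same-numbered libraries correlated at 0.08, 0.17 and 0.17, and TAB 2 correlated best with Sham 2, TAB 3 with Sham 3, and TAB 1 also with Sham 3 (0.10). Of 155 named genes called, 105 were called in the same direction under each alternative that gave a value. One changed sign: Atp5b, -0.19 as reported, was 0.03 under quantile normalization (adjusted p = 0.51), and the cause was not tested. Depth limits low genes, for which 1 FPKM on a 2 kb transcript is 21.6 to 24.4 fragments.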

Other observations

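The test of a shared severity scale was chosen after its values were seen. Gene groups outside the heart muscle and matrix programs also differed between TAB and Sham. Cytosolic ribosomal protein genes were higher in 20 of 44, lower in 0 and not called in 24 (30 higher adjusted over the list alone, median log2 fold change 0.15, camera adjusted p = 5.38e-05, and adjusted p = 0.60 with an estimated correlation). Rpl3 rose from 128 ± 9.58 (SD, n = 4) to 185 ± 7.64 (SD, n = 3). The number of higher members was 5 under median-of-ratios rescaling and under eBayes without trend and robust, 12 without a filter, 9 without Sham 1, 7 without TAB 2 and 8 without Sham 3, TAB 1 or TAB 3. Proteasome genes were higher in 8 of 31, lower in 0 and not called in 23 (10 adjusted over the list alone, median 0.10, camera adjusted p = 0.00391, and adjusted p = 0.48 with an estimated correlation), among them Psmd8 (0.23 ± 0.04) and Psmd13 (0.21 ± 0.04). That count was 2 under median-of-ratios rescaling and under eBayes without trend and robust, 5 under quantile normalization, 3 without Sham 1 or TAB 1, 4 without Sham 3 or TAB 3 and 5 without Sham 4. Cell cycle genes were higher in 7 of 19, lower in 1 (the inhibitor Cdkn1b) and not called in 11 (8 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 0.00776, and adjusted p = 0.43 with an estimated correlation). The cyclin gene Ccnd2 rose by 0.53 ± 0.07 and Mcm6 by 0.48 ± 0.10. Cdkn1b (-0.21 ± 0.06), chosen after its values were seen, lost its call without Sham 1, Sham 4, TAB 1 or TAB 3 (adjusted p from 0.053 to 0.10). At a mean FPKM of at least 5 only 2 cell cycle genes were higher (camera adjusted p = 0.32).

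Interferon response genes, which antiviral signals induce, were higher in 8 of 23, lower in 0 and not called in 15 (13 adjusted over the list alone, median 0.34, camera adjusted p = 0.000274, and adjusted p = 0.46 with an estimated correlation). Oasl2 rose from 2.61 ± 0.163 to 4.14 ± 0.202 and Ifit2 from 3.68 ± 0.539 to 6.11 ± 0.483. Without Sham 4, the Sham library with the highest levels, 17 of the 23 were called higher, and without Sham 1, TAB 1 or TAB 3 5 were. At a mean FPKM of at least 5 only 2 were higher (camera adjusted p = 0.20), and under quantile normalization 5. Of 18 genes of the renin-angiotensin and adrenergic systems 2 were higher, 3 lower and 13 not called, also when adjusted over the list alone (median 0.00, mean -0.02, camera adjusted p = 0.22). Ace, the angiotensin-converting enzyme gene, rose from 14.2 ± 0.514 to 23.8 ± 2.82, and the adrenergic receptor genes Adra1a and Adra1b fell by 0.46 ± 0.06 and 0.71 ± 0.13. Corin, whose product cleaves the Nppa precursor, fell from 71.9 ± 3.86 to 54.7 ± 5.21. The other higher member was Ednrb (0.41 ± 0.13), chosen after its values were seen, which lost its call without any library other than Sham 3 (adjusted p from 0.056 to 0.16), and also without a filter, under both rescalings, under eBayes without trend and robust and with the atrial covariate (0.051 to 0.089). Of 23 genes of the unfolded protein and heat shock response 1 was higher (Atf4, 0.43 ± 0.07), 3 lower and 19 not called, also when adjusted over the list alone. Herpud1 fell from 180 ± 9.27 to 118 ± 5.25, Canx by 0.28 ± 0.04 and Dnajb9 by 0.26 ± 0.07. Dnajb9 lost its call without Sham 1, Sham 4, TAB 2 or TAB 3 (adjusted p from 0.058 to 0.11), without a filter (0.065) and under eBayes without trend and robust (0.056). Without Sham 1, Sham 2 or TAB 1 2 were higher. The list was not called (camera adjusted p = 0.11, and called lower without Sham 2, Sham 3 or TAB 3 at camera adjusted p from 0.014 to 0.039). Without both Sham 2 and TAB 3 the list was called lower at camera adjusted p = 0.0033. Of 21 oxidative stress genes 3 were higher, 4 lower and 14 not called (4 and 4 adjusted over the list alone, camera adjusted p = 0.52). Gpx1 (0.56 ± 0.08), Gpx3 (0.48 ± 0.11) and Gpx4 (0.13 ± 0.04) rose. Gstm1 (-0.44 ± 0.05), Sod2 (-0.23 ± 0.04), Gsta4 (-0.20 ± 0.04) and Sod1 (-0.18 ± 0.05) fell. Gpx3, Gpx4 and Sod1 were chosen after their values were seen. Calls were lost for Gpx3 without Sham 1 or TAB 1 (adjusted p = 0.051 and 0.052), for Gpx4 without any library other than Sham 2 (0.064 to 0.10), for Gsta4 without TAB 1 (0.052) and for Sod1 without TAB 1 or TAB 3 (0.091 and 0.074). Gpx4 also lost its call under median-of-ratios rescaling (0.19), under eBayes without trend and robust (0.11) and with the atrial covariate (0.059), and Sod1 under eBayes without trend and robust (0.061). Without Sham 3 5 were higher, without Sham 1 1 was, and without TAB 1 1 was higher and 2 lower. Of 17 immediate early genes 3 were higher and 14 not called (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.60), and Ier5, Jun and Ier2 rose by 0.61 ± 0.10, 0.56 ± 0.13 and 0.24 ± 0.06. Jun lost its call without Sham 1, TAB 1 or TAB 2 (adjusted p from 0.054 to 0.067), and Ier2 without TAB 2 or TAB 3 (0.053 and 0.072), under median-of-ratios rescaling (0.051) and under quantile normalization (0.068). Without TAB 2 1 was higher, without Sham 3 5 were, and without Sham 2 or Sham 4 1 was lower. Of 17 atrophy and autophagy genes Ctsl (0.20 ± 0.04) was higher, Fbxo32 (-0.39 ± 0.10) lower and 15 not called, also when adjusted over the list alone (camera adjusted p = 0.78). Without Sham 3 or TAB 2 3 were higher, and without TAB 1 2 were. None of 18 circadian clock genes was called with limma, and 3 had an unadjusted p under 0.05 (0 adjusted over the list alone, camera adjusted p = 0.71), and without TAB 3 1 was higher.

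TAB 2 shifted less than TAB 1 and TAB 3 in matrix genes. The median shift from the Sham mean of the 32 matrix genes was 1.04 in TAB 1, 0.51 in TAB 2 and 0.86 in TAB 3, and TAB 2 had the smallest shift in 31 of the 32. It also had the smallest shift in 17 of 18 hypertrophy genes, 15 of 17 macrophage markers and 43 of 52 oxidative phosphorylation genes, with ratios of the TAB 2 median to the mean of TAB 1 and TAB 3 of 0.51, 0.29 and 0.16. That ratio was near 1 in other lists, at 1.08 for branched-chain amino acid and ketone catabolism, 0.99 for potassium and sodium channels and 1.01 for interferon response genes, and above 1 in some, at 1.74 for the adult sarcomere and 1.45 for cytosolic ribosomal proteins. A milder load in TAB 2 that scales all groups of genes alike might be a cause, which was tested on the matrix (ratio 0.53) and fatty acid oxidation genes (0.95) only, a difference of 0.41 (95% bootstrap interval over genes 0.13 to 0.52). One scale would put the TAB 2 median of the fatty acid oxidation genes at -0.19, and the observed value lay 0.15 lower, within the half-width of 0.16 that the spread between Sham libraries gives, so a single library leaves the question open.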
